A study of Homo sapiens with 15 samples.

How the data were processed

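RNA of MOLM-13 cells was sequenced 3 days after lentiviral transduction with empty vector, RUNX1A, RUNX1B, RUNX1C or the RUNX1C construct labelled NDel (5 groups of 3 libraries, 15 in all). Per the labels, libraries were directional, made from polyA-selected RNA and read as 150 bp pairs.

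The authors' notes name RSEM 1.2.4, TopHat2 2.0.8b, TopHat and the hg38 genome, without giving each tool's role or order, and the annotation version is not given in the sources used here. The deposited expression table is named as counts, but its values have 2 decimals and the library totals run from 999999 to 1000001, the fixed total of TPM values within rounding, so the deposited values were treated as TPM. The authors also deposited 3 tables of differences between constructs with the column names of DESeq2. Per the file headers these hold a mean level (baseMean), a log2 fold change with its standard error (log2 units), a Wald statistic (a score), a p-value and an adjusted p-value. The tables hold only genes with a p-value under 0.05 and a change of more than 2-fold. Values from them are named as the authors' and were not recomputed.

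The test planned before the data were examined needed counts (a quasi-likelihood test in edgeR) and was replaced by limma 3.58.1 in R 4.3.3, since TPM values are not counts. Genes with at least 0.5 TPM in at least 3 libraries were tested. Libraries were scaled by a trimmed mean of log ratios to the mean library (30% of the log ratios and 5% of the mean levels trimmed at each end), and log2 of TPM plus 1 was fitted with a mean per group over all 15 libraries, with empirical Bayes variances that follow the mean level. P-values were adjusted by the Benjamini-Hochberg method within each comparison. TPM values printed are the deposited ones, before scaling. TPM keeps no sequencing depth, so the depth per library is unknown and no precision was derived from it.

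The 8 comparisons were each construct against empty vector, the pairs RUNX1C and RUNX1A, RUNX1C and RUNX1B, and RUNX1A and RUNX1B, and RUNX1C against its NDel form. A test of any difference among the 5 groups was added. Lists of genes (33 with at least 5 tested members), written before the data were examined and without RUNX1, were tested with camera at a preset correlation of 0.01 and again with a correlation estimated for each list, with adjustment over the lists of a comparison. Correlations between changes against control were set beside 100 simulations of unchanged groups. In each simulation the groups shared 3 mock controls, drawn from the deviations of all 15 libraries and not the real controls.

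Named genes followed a rule set before the data were examined. RUNX1 and BTG2 were always eligible. Against control, the 8 higher and 8 lower genes with the largest log2 fold change were eligible if the adjusted p was under 0.05, the mean was at least 1 TPM in the higher group and the 3 libraries of each group did not overlap; between constructs it was 5 and 5. For each list that was called, or had at least 3 members with an adjusted p under 0.05, up to 3 members with the smallest adjusted p were eligible. RUNX1, unnamed loci and pseudogenes were left out of the ranking. The value of 1 gene eligible under the rule is not reported here. The rule was written for CPM and was applied to TPM.

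Alternatives were median-ratio scaling, no scaling, no filter, a filter at 1 TPM, the replicate number as a block, the 6 libraries of a comparison alone, a 1.5-fold minimum, an estimated list correlation and leaving out each library. Pseudocounts of 0.1 and 2 TPM, removal of GC content and length trends, and no variance trend were added after the data were seen. GC content, length and positions came from GENCODE release 29, matched for 15285 genes (97.3%) by gene identifier, and the trends were removed with natural splines of 5 degrees of freedom.

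The procedure was tested on simulated data with 200 changed genes, all with a mean of at least 2 TPM. It recovered 92.5% of those changed 1.5-fold, 94.0% at 2-fold and 100% at 4-fold, and 5.63% of its calls were unchanged genes. The noise was independent between genes, and each real comparison called at least 4118 genes. These rates may therefore not carry over to the real comparisons or to weaker genes. With a simulated GC trend 5560 unchanged genes were called, and 0 after the trend was removed. Tables were handled with Python 3.11.15 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.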

Results

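RNA from MOLM-13 cells, an established human acute myeloid leukaemia line with monocytic features, was sequenced after transduction with a lentivirus that expressed an isoform of the transcription factor RUNX1 together with a puromycin resistance gene and the green fluorescent protein ZsGreen. The 5 groups were empty vector (control), RUNX1A, RUNX1B, RUNX1C and a RUNX1C construct labelled NDel, which the file header calls an N-terminal mutant, with 3 libraries each and 15 in all. RUNX1A lacks the C-terminal activation region of the longer isoforms, and RUNX1B and RUNX1C differ at the N-terminus. Harvest followed transduction by 3 days, and the labels mention no selection step and do not say what NDel removes. Each library was a list of 61852 genes in TPM, a relative unit corrected for gene length that keeps no total count, so the depth is unknown and no counting intervals are given. Between 12673 and 13037 genes per library reached 1 TPM. The labels do not say that replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

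TPM values below are the mean ± SD of a group (n = 3). Log2 fold changes were taken on log2 of TPM plus 1, so they understate the change of weakly expressed genes, and each carries its standard error (SE). "Higher" and "lower" refer to genes with a limma adjusted p under 0.05 among the 15707 genes tested. Gene lists were fixed before the data were examined and were tested with camera at a preset correlation between genes. A correlation estimated for each list gave far larger p-values, and not only for the lists of replication and mitosis. Against control 9 of 16 called lists kept the call with RUNX1A, 5 of 11 with RUNX1B, 7 of 14 with RUNX1C and 4 of 10 with RUNX1C NDel. The adjusted p of a list is that of the preset correlation unless an estimated one or another setting is named. The number of genes at 1.5-fold depends on the constant added to TPM. With 2 in place of 1 it fell in every comparison. Against control it was then 414 with RUNX1A, 293 with RUNX1B, 1461 with RUNX1C and 612 with RUNX1C NDel. For RUNX1C against control a constant of 0.1 gave 2737 in place of 1916. With 0.1 in place of 1 it was 1006 in place of 606 with RUNX1A, 811 in place of 436 with RUNX1B and 1530 in place of 917 with RUNX1C NDel against control. Between constructs it was 1446 in place of 932 for RUNX1C and RUNX1B, 2148 in place of 1410 for RUNX1A and RUNX1B and 969 in place of 592 for RUNX1C and RUNX1C NDel. A list's count of members "adjusted over the list alone" stands beside the count over all genes.

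RUNX1 (ENSG00000159216.19, chromosome 21, 34787801 to 36004667, minus strand, hg38) was higher with each of the 4 RUNX1 constructs than with empty vector. The control libraries held 50.3 ± 3.44 TPM of RUNX1 (SD, n = 3). The level was 673 ± 36.4 TPM with RUNX1A, 528 ± 21.0 with RUNX1B, 378 ± 16.1 with RUNX1C and 359 ± 13 with RUNX1C NDel. The log2 fold changes against control were 3.79 (adjusted p = 7.77e-15), 3.29 (adjusted p = 4.74e-14), 2.85 (adjusted p = 1.93e-14) and 2.77 (adjusted p = 1.26e-13), each with an SE of 0.04. RUNX1 did not pass the test between RUNX1C and RUNX1C NDel (log2 difference 0.07, SE 0.04, adjusted p = 0.233). The lowest RUNX1A library (639 TPM) lay above the highest library of any other group (552 TPM). The gene-level values do not separate the isoforms or the transgene from the cell's own RUNX1.

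**Figure D1:**
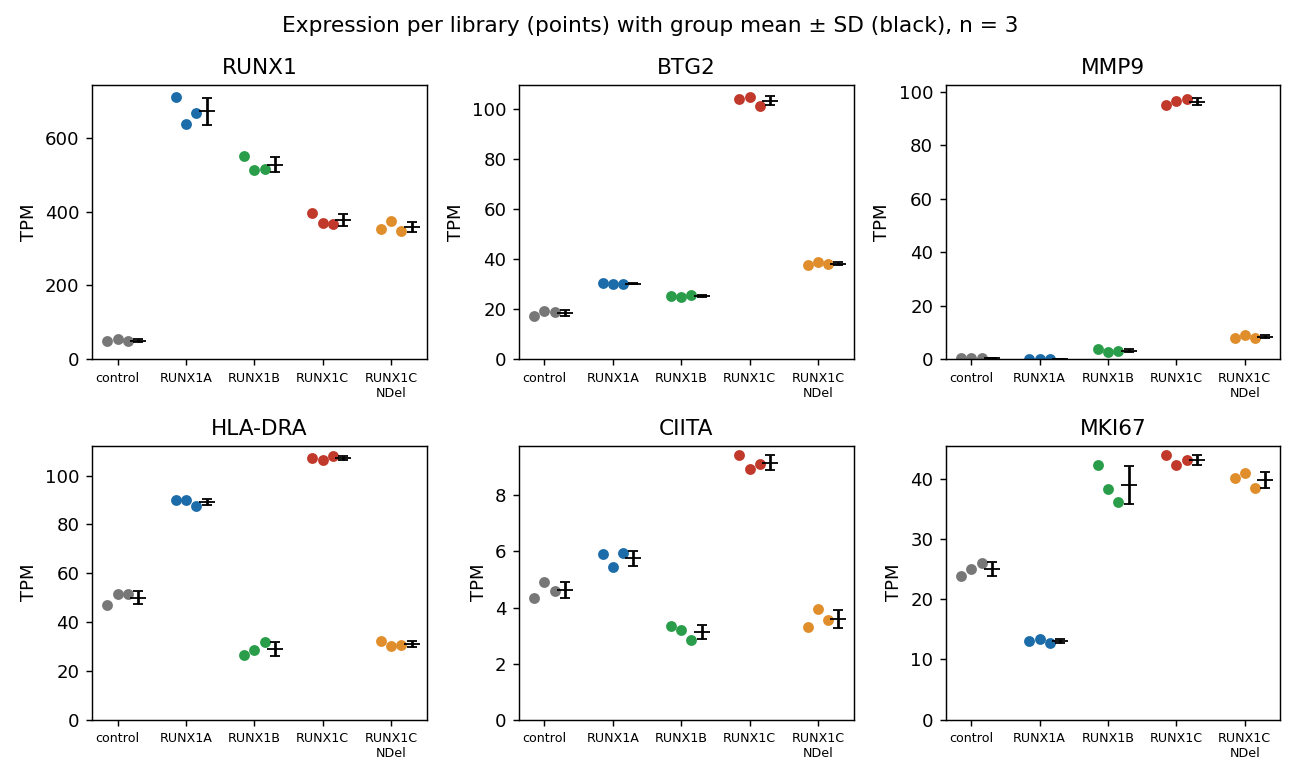
TPM of RUNX1, BTG2, MMP9, HLA-DRA, CIITA and MKI67 in each library (points) of the 5 groups (x axis), with the group mean and SD in black (n = 3). BTG2 stands at 103 TPM and MMP9 at 96.3 TPM with RUNX1C, above all other groups.

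The 5 groups differed in 10274 of the 15707 genes tested (adjusted p under 0.05 in limma's test of any difference among groups). The first principal component held 43.7% of the variance and the second 14.3%. Correlations between libraries, taken across genes, ran from 0.989 to 0.993 within groups and from 0.960 to 0.992 between groups. Genes are not independent replicates, and these values describe similarity only.

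**Figure D2:**
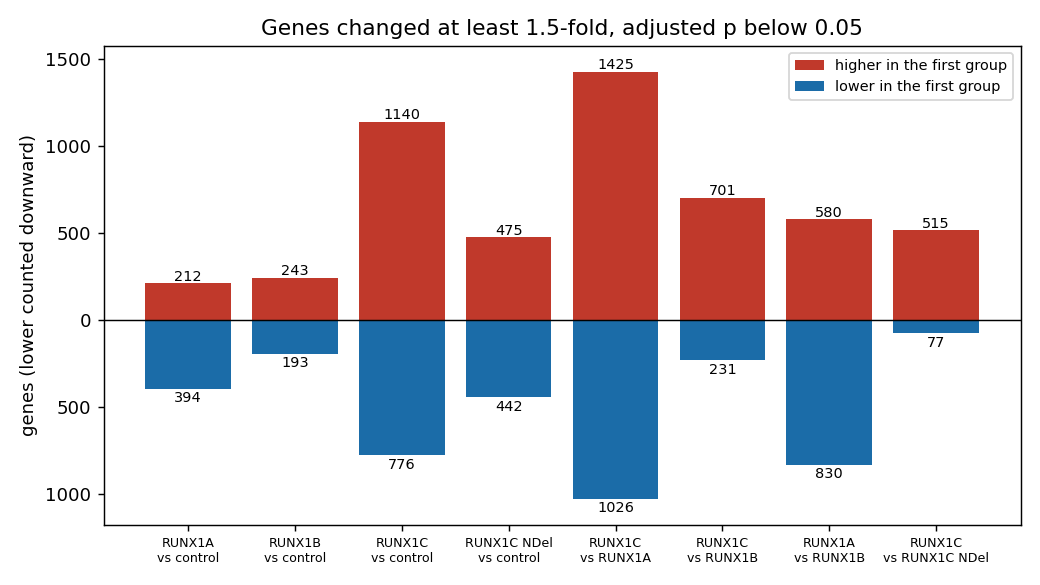
Number of genes (y axis) at least 1.5-fold higher (upward bars) or lower (downward bars) in the first group of each comparison (x axis), at an adjusted p under 0.05. The counts run from 77 genes lower with RUNX1C than with RUNX1C NDel to 1425 genes higher with RUNX1C than with RUNX1A.

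The comparison of RUNX1A with control asked what the short isoform changed. Genes of DNA replication and mitosis were lower with RUNX1A. TYMS, the thymidylate synthase, fell from 104 ± 3.73 to 49.3 ± 0.214 TPM (log2 fold change -0.99, SE 0.03, adjusted p = 1.62e-10), and the mitotic kinesin gene KIF2C fell from 18.0 ± 0.191 to 7.64 ± 0.448 TPM. BCL2, an inhibitor of apoptosis, fell from 24.1 ± 1.81 to 8.88 ± 0.508 TPM, and MPO, the myeloperoxidase of granules, from 9.72 ± 0.494 to 1.7 ± 0.161 TPM. The largest rises included FCRLA (4.89 ± 0.572 to 17.8 ± 1.72 TPM), the cell surface gene CD48 (1.90 ± 0.170 to 7.74 ± 0.249 TPM) and FOS, a transcription factor of the immediate early response (13.5 ± 0.986 to 38.4 ± 2.91 TPM). Among the genes named by the rule for the largest changes, CHI3L1, a secreted chitinase-like protein, fell most (81.3 ± 1.22 to 15.1 ± 0.854 TPM, log2 fold change -2.29, SE 0.04, adjusted p = 9.06e-13).

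Among the gene lists, all 42 measured members of the G1/S and replication list were lower with RUNX1A than in control (42 adjusted over the list alone; median log2 fold change -0.69, adjusted p = 8.75e-38, and adjusted p = 1.94e-05 with an estimated correlation). In the G2/M list 38 of 40 members were lower and none higher (38 adjusted over the list alone; median -0.84, adjusted p = 8.75e-38, and adjusted p = 2.92e-05 with an estimated correlation). The monocyte and macrophage list had 15 of 26 members higher and 3 lower (15 and 4 adjusted over the list alone; adjusted p = 2.6e-05), with the integrin ITGAM at 21.3 ± 1.30 against 13.7 ± 0.390 TPM and CTSB, a lysosomal protease, at 179.6 ± 1.79 against 137 ± 3.46 TPM. The granulocyte list had 2 of 15 members higher and 10 lower (2 and 11 adjusted over the list alone; adjusted p = 9.04e-05). Antigen presentation genes were higher in 9 of 16 cases and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000618), among them HLA-DRA, an MHC class II chain (89.1 ± 1.33 against 50.1 ± 2.61 TPM). Immediate early genes were higher in 12 of 21 cases and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 1.49e-05). Of 29 p53 targets 14 were higher and 3 lower (17 and 6 adjusted over the list alone; adjusted p = 0.000343), with the CDK inhibitor gene CDKN1A at 406 ± 10.4 against 274 ± 15.5 TPM. The unfolded protein and stress list had 1 of 24 members higher and 12 lower (1 and 13 adjusted over the list alone; adjusted p = 2e-05), with the chaperone gene CALR at 309 ± 7.12 against 657 ± 22.6 TPM. Cholesterol synthesis genes were higher in 1 and lower in 13 of 23 cases (2 and 15 adjusted over the list alone; adjusted p = 2.69e-05).

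With RUNX1A, 4859 genes passed the test, 2344 higher and 2515 lower, and 212 and 394 of these changed at least 1.5-fold. Of the 33 lists 16 were called, and the 9 just described were also called with an estimated correlation. Transcripts encoded by mitochondria took 7.26% to 8.34% of the TPM of the RUNX1A libraries against 6.21% to 6.46% in control, and 9 of the 13 such genes were higher (12 adjusted over the list alone; adjusted p = 4.95e-06, and adjusted p = 0.243 with an estimated correlation). Without scaling between libraries the share of called genes that were higher was 27.7% in place of 48.2%, and 151 and 482 genes were at least 1.5-fold higher and lower.

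The comparison of RUNX1B with control asked what a full-length isoform changed. CLEC10A, a lectin receptor of dendritic cells and macrophages (ENSG00000132514.14, chromosome 17, 7074537 to 7080307), rose from 2.79 ± 0.286 to 25.9 ± 0.640 TPM (log2 fold change 2.76, SE 0.06, adjusted p = 7.04e-12). The calprotectin genes S100A8 and S100A9 rose from 45.8 ± 3.52 to 275 ± 25.1 TPM and from 36.1 ± 2.91 to 254 ± 23.1 TPM, and LYZ, the lysozyme gene, from 499 ± 31.5 to 1871 ± 76.7 TPM. The largest falls included BPI, a bactericidal protein of neutrophil granules (14.7 ± 0.450 to 2.86 ± 0.208 TPM, log2 fold change -2.09, SE 0.07, adjusted p = 2.15e-10), and the surface antigen gene CD52 (29.3 ± 1.89 to 6.97 ± 0.344 TPM).

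In the RUNX1B libraries, 19 of 26 monocyte and macrophage genes were higher than in control and 3 lower (21 and 4 adjusted over the list alone; median log2 fold change 0.41, adjusted p = 1.23e-09), with IRF8, a transcription factor of monocytes and dendritic cells, at 391 ± 13 against 259.8 ± 11.6 TPM. The G2/M list had 36 of 40 members higher and none lower (37 adjusted over the list alone; median 0.33, adjusted p = 2.86e-20), and the G1/S list had 29 of 42 higher and none lower (33 adjusted over the list alone; median 0.19, adjusted p = 1.67e-11). The proliferation marker MKI67 stood at 38.9 ± 3.10 against 25.0 ± 1.12 TPM. Cholesterol synthesis genes were higher in 17 of 23 cases and lower in none (19 adjusted over the list alone; adjusted p = 1.42e-09). Of 29 p53 targets 2 were higher and 15 lower (2 and 15 adjusted over the list alone; adjusted p = 0.000454), among them SESN1 (20.8 ± 1.18 against 35.6 ± 0.869 TPM). In the list of MYC targets and ribosome biogenesis genes 22 of 34 members were lower and 1 higher (24 and 1 adjusted over the list alone; adjusted p = 1.23e-09, and adjusted p = 0.0729 with an estimated correlation). Antigen presentation genes went both ways, with 5 of 16 higher and 8 lower (5 and 8 adjusted over the list alone), and the list was not called (median -0.24, mean 0.02, adjusted p = 0.183).

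With RUNX1B, 4118 genes passed the test, 2119 higher and 1999 lower, and 243 and 193 of these changed at least 1.5-fold. Camera called 11 of the 33 lists, and those called also with an estimated correlation were the G1/S, G2/M, monocyte, p53 and cholesterol lists. Without scaling between libraries the share of called genes that were higher was 75.0% in place of 51.5%, and 334 and 148 genes were at least 1.5-fold higher and lower. Ribosomal protein genes took 40.2% to 42.2% of the TPM against 43.7% to 44.1% in control, with 18 of 36 lower and none higher (27 adjusted over the list alone; adjusted p = 2.94e-07, and adjusted p = 0.183 with an estimated correlation).

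The comparison of RUNX1C with control addressed the isoform with the longest N-terminus, and it gave the largest changes of the 4 comparisons with control by number of genes. MMP9, a secreted matrix metalloproteinase (ENSG00000100985.7, chromosome 20, 46008908 to 46016561), rose from 0.297 ± 0.0306 to 96.3 ± 1.33 TPM (log2 fold change 6.20, SE 0.07, adjusted p = 2.32e-15). CLEC10A rose from 2.79 ± 0.286 to 123 ± 1.25 TPM, LYZ from 499 ± 31.5 to 5300.1 ± 233 TPM and GNLY, a cytolytic granule protein, from 0.170 ± 0.165 to 23.1 ± 0.913 TPM. BTG2, an antiproliferative gene and p53 target (ENSG00000159388.6, chromosome 1, 203305491 to 203309602), rose from 18.4 ± 1.05 to 103 ± 1.86 TPM (log2 fold change 2.39, SE 0.03, adjusted p = 2.32e-15). MYC, the transcription factor that drives ribosome production, fell from 569 ± 6.92 to 228 ± 5.27 TPM (log2 fold change -1.35, SE 0.04, adjusted p = 2.12e-11). The largest falls included DYSF, a membrane repair gene (14.9 ± 0.434 to 1.87 ± 0.1 TPM), and ECM1 (40.5 ± 0.909 to 6.95 ± 0.451 TPM).

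In this comparison 23 of 26 monocyte and macrophage genes were higher with RUNX1C and 3 lower (23 and 3 adjusted over the list alone; median log2 fold change 1.63, adjusted p = 2.4e-13), with IRF8 at 706 ± 7.42 against 259.8 ± 11.6 TPM. Antigen presentation genes were higher in 14 of 16 cases and lower in 1 (14 and 2 adjusted over the list alone; median 0.90, adjusted p = 2.87e-06), with IRF4, a transcription factor of lymphoid and dendritic cells, at 8.77 ± 0.380 against 0.310 ± 0.140 TPM. The NF-kB and inflammation list had 14 of 20 members higher and 2 lower (14 and 2 adjusted over the list alone; adjusted p = 0.000858), among the higher ones PLAUR, the urokinase receptor gene (101 ± 4.16 against 37.5 ± 0.760 TPM). Of 24 genes downstream of FLT3, MAPK and STAT5, 15 were higher and 6 lower (15 and 7 adjusted over the list alone; adjusted p = 0.0127), with the phosphatase gene DUSP4 at 36.3 ± 0.623 against 4.17 ± 0.113 TPM. MYC targets and ribosome biogenesis genes were lower in 33 of 34 cases and higher in none (33 adjusted over the list alone; median -0.62, adjusted p = 5.33e-17). The G2/M list had 34 of 40 members higher and 1 lower (36 and 1 adjusted over the list alone; median 0.34, adjusted p = 1.4e-09), while the G1/S list had 5 of 42 higher and 16 lower (3 and 16 adjusted over the list alone; median -0.08, adjusted p = 0.044). The G1/S call was lost with an estimated correlation (adjusted p = 0.194 with an estimated correlation) and without scaling between libraries (adjusted p = 0.142); over the alternatives its adjusted p ran from 0.0463 to 0.194. Cholesterol synthesis genes were higher in 17 of 23 cases and lower in 1 (17 and 1 adjusted over the list alone; adjusted p = 7.03e-05).

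With RUNX1C, 8070 genes passed the test, 4006 higher and 4064 lower, and 1140 and 776 of these changed at least 1.5-fold. Of the 33 lists 14 were called, and 7 of these were also called with an estimated correlation, namely the G2/M, MYC, monocyte, antigen presentation, NF-kB, FLT3 and cholesterol lists. Ribosomal protein genes took 40.8% to 41.8% of the TPM, and 20 of 36 were lower and none higher than in control (21 adjusted over the list alone; adjusted p = 0.00246, and adjusted p = 0.439 with an estimated correlation).

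The comparison of RUNX1C NDel with control showed what the N-terminal mutant changed. CLEC10A rose from 2.79 ± 0.286 to 53.1 ± 1.54 TPM (log2 fold change 3.80, SE 0.06, adjusted p = 1.45e-13), CHI3L1 from 81.3 ± 1.22 to 660.2 ± 12.4 TPM, S100A8 from 45.8 ± 3.52 to 432 ± 34.9 TPM and MMP9 from 0.297 ± 0.0306 to 8.28 ± 0.569 TPM. BTG2 rose from 18.4 ± 1.05 to 38.1 ± 0.655 TPM (log2 fold change 0.97, SE 0.03, adjusted p = 9.59e-12). BPI fell from 14.7 ± 0.450 to 1.63 ± 0.187 TPM, and SELPLG, the P-selectin ligand gene, from 52.4 ± 1.83 to 13.9 ± 1.7 TPM. The MHC class II genes HLA-DRA (50.1 ± 2.61 to 31.1 ± 1.15 TPM) and HLA-DRB1 (28.1 ± 0.910 to 18.0 ± 0.810 TPM) also fell.

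Among the lists for RUNX1C NDel, 22 of 26 monocyte and macrophage genes were higher than in control and 3 lower (22 and 3 adjusted over the list alone; median log2 fold change 0.96, adjusted p = 1.66e-11), with LYZ at 2363 ± 71.2 against 499 ± 31.5 TPM and ITGAM, a lower member, at 2.95 ± 0.201 against 13.7 ± 0.390 TPM. The G2/M list had 37 of 40 members higher and none lower (37 adjusted over the list alone; median 0.42, adjusted p = 2.21e-17), and the G1/S list 36 of 42 higher and none lower (36 adjusted over the list alone; median 0.26, adjusted p = 1.06e-11). The replication helicase gene MCM5 stood at 81.9 ± 1.28 against 59.1 ± 0.841 TPM. Cholesterol synthesis genes were higher in 16 of 23 cases and lower in none (17 adjusted over the list alone; adjusted p = 2.26e-06). MYC targets and ribosome biogenesis genes were lower in 27 of 34 cases and higher in 1 (28 and 1 adjusted over the list alone; adjusted p = 2.82e-10, and adjusted p = 0.086 with an estimated correlation). Antigen presentation genes were higher in 5 of 16 cases and lower in 8 (5 and 8 adjusted over the list alone), and the list was not called (median -0.16, mean 0.16, adjusted p = 0.482).

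With RUNX1C NDel, 5996 genes passed the test, 3116 higher and 2880 lower, and 475 and 442 of these changed at least 1.5-fold. Camera called 10 of the 33 lists, and the monocyte, G2/M, G1/S and cholesterol lists were the 4 called also with an estimated correlation.

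**Figure D3:**
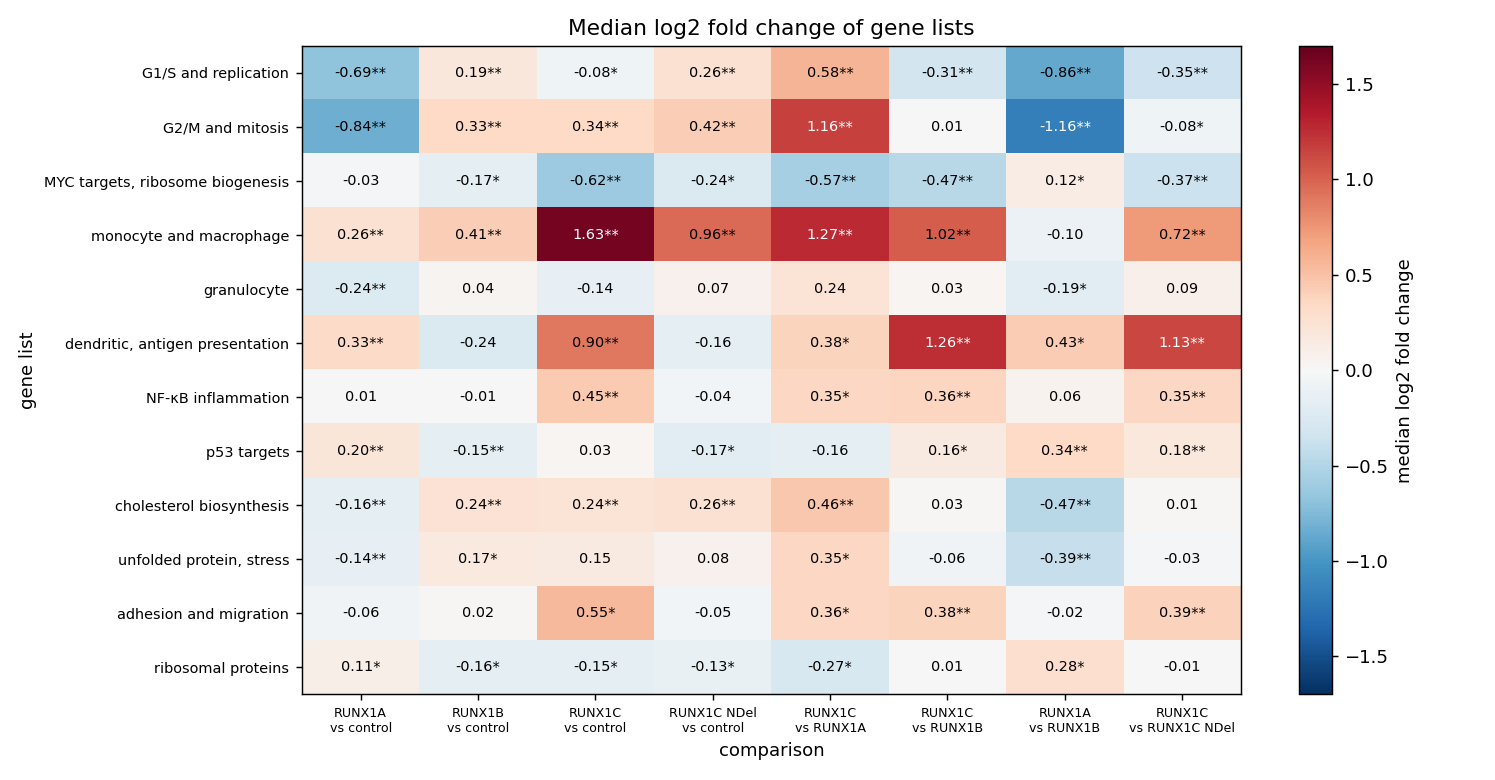
Median log2 fold change (colour and number) of 12 gene lists (y axis) in the 8 comparisons (x axis). Lists called by camera carry *, and those called also with an estimated correlation carry **; the monocyte list reaches 1.63 with RUNX1C against control.

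The comparison of RUNX1C with RUNX1A set the longest isoform against the shortest. RUNX1 levels differed as well (368 to 396 TPM in the RUNX1C libraries, 639 to 711 with RUNX1A). This comparison alone does not separate isoform from RUNX1 level. MMP9 stood at 96.3 ± 1.33 TPM with RUNX1C and 0.0967 ± 0.0252 with RUNX1A (log2 fold change 6.44, SE 0.07, adjusted p = 5.17e-16). CHI3L1 stood at 545 ± 6.91 against 15.1 ± 0.854 TPM and MCEMP1, a mast cell and monocyte membrane protein gene, at 133 ± 0.853 against 4.05 ± 0.116 TPM. BTG2 was higher with RUNX1C (103 ± 1.86 against 30.1 ± 0.268 TPM, log2 fold change 1.64, SE 0.03, adjusted p = 2.23e-14). Genes lower with RUNX1C included FABP3, a fatty acid binding protein gene (0.487 ± 0.110 against 13.6 ± 0.387 TPM), and FCRLA (0.967 ± 0.245 against 17.8 ± 1.72 TPM).

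Between RUNX1C and RUNX1A, 38 of 40 G2/M genes were higher with RUNX1C and none lower (38 higher and 1 lower adjusted over the list alone; median log2 fold change 1.16, adjusted p = 1.34e-21), with CDC20, an activator of the anaphase-promoting complex, at 56.3 ± 1.44 against 20.1 ± 0.805 TPM. G1/S genes were higher in 40 of 42 cases and lower in none (40 adjusted over the list alone; median 0.58, adjusted p = 1.79e-14). Monocyte and macrophage genes were higher in 23 of 26 cases and lower in 3 (23 and 3 adjusted over the list alone; median 1.27, adjusted p = 5.4e-10). The cholesterol list had 18 of 23 members higher and 1 lower (19 and 1 adjusted over the list alone; median 0.46, adjusted p = 4.79e-07). MYC targets and ribosome biogenesis genes were lower in 32 of 34 cases and higher in none (32 lower and 1 higher adjusted over the list alone; median -0.57, adjusted p = 1.42e-14). Antigen presentation genes were higher in 10 of 16 cases and lower in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.0203, and adjusted p = 0.056 with an estimated correlation).

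In this pair 8674 genes passed the test, 4392 higher and 4282 lower with RUNX1C, and 1425 and 1026 of these differed at least 1.5-fold. Of the 33 lists 15 were called, 5 of them also with an estimated correlation, namely the G2/M, G1/S, monocyte, cholesterol and MYC lists. Without scaling between libraries the share of called genes that were higher was 65.2% in place of 50.6%, and 1772 and 735 genes were at least 1.5-fold higher and lower. Mitochondrially encoded genes were lower with RUNX1C in 8 of 13 cases and higher in none (8 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.487 with an estimated correlation).

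The comparison of RUNX1C with RUNX1B set apart the 2 isoforms that differ at the N-terminus. RUNX1 levels differed as well (368 to 396 TPM in the RUNX1C libraries, 515 to 552 with RUNX1B). This comparison alone does not separate isoform from RUNX1 level. MMP9 stood at 96.3 ± 1.33 TPM with RUNX1C and 3.08 ± 0.516 with RUNX1B (log2 fold change 4.61, SE 0.07, adjusted p = 7.14e-14). GNLY stood at 23.1 ± 0.913 against 0.423 ± 0.174 TPM, and HLA-DRA at 107 ± 0.905 against 29 ± 2.72 TPM. BTG2 was higher with RUNX1C (103 ± 1.86 against 25.1 ± 0.387 TPM, log2 fold change 2.04, SE 0.03, adjusted p = 3.45e-14), and MYC lower (228 ± 5.27 against 424 ± 18.7 TPM). FOS was also lower with RUNX1C (7.60 ± 0.634 against 18.8 ± 2.42 TPM).

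With RUNX1C 23 of 26 monocyte and macrophage genes were higher than with RUNX1B and 2 lower (23 and 2 adjusted over the list alone; median log2 fold change 1.02, adjusted p = 1.81e-15). Antigen presentation genes were higher in 13 of 16 cases and lower in 1 (13 and 1 adjusted over the list alone; median 1.26, adjusted p = 7.74e-09). The NF-kB and inflammation list had 13 of 20 members higher and 2 lower (13 and 3 adjusted over the list alone; adjusted p = 0.000274), and the adhesion and migration list 10 of 16 higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 0.00162), with the integrin gene ITGB7 at 81.2 ± 3.35 against 25.5 ± 0.944 TPM. CDK inhibitors and genes of quiescence were higher in 12 of 16 cases and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 6.58e-05), with CDKN1A at 292 ± 9.18 against 227 ± 10.6 TPM. All 34 MYC targets and ribosome biogenesis genes were lower (34 adjusted over the list alone; median -0.47, adjusted p = 4.73e-19), and 35 of 42 G1/S genes were lower and none higher (37 adjusted over the list alone; median -0.31, adjusted p = 2.07e-13). The G2/M list was not called, with 4 of 40 members higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.807).

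Between RUNX1C and RUNX1B 6392 genes passed the test, 3154 higher and 3238 lower with RUNX1C, and 701 and 231 of these differed at least 1.5-fold. Camera called 12 of the 33 lists, and the 7 called lists just described were also called with an estimated correlation.

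The comparison of RUNX1A with RUNX1B set the short isoform against a full-length one. RUNX1 levels differed as well (639 to 711 TPM in the RUNX1A libraries, 515 to 552 with RUNX1B). This comparison alone does not separate isoform from RUNX1 level. CHI3L1 stood at 15.1 ± 0.854 TPM with RUNX1A and 332 ± 4.52 with RUNX1B (log2 fold change -4.22, SE 0.04, adjusted p = 3.86e-16), and S100A8 at 22.4 ± 1.57 against 275 ± 25.1 TPM. BCL2 stood at 8.88 ± 0.508 against 37.0 ± 2.33 TPM, and FLT3, a receptor tyrosine kinase gene, at 80.5 ± 1.25 against 192 ± 6.86 TPM. Genes higher with RUNX1A included FCRLA (17.8 ± 1.72 against 1.28 ± 0.0173 TPM), CD52 (57.0 ± 7.13 against 6.97 ± 0.344 TPM) and HLA-DRA (89.1 ± 1.33 against 29 ± 2.72 TPM). BTG2 differed by 0.40 on the log2 scale (30.1 ± 0.268 against 25.1 ± 0.387 TPM, SE 0.03, adjusted p = 3.73e-08).

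All 42 G1/S genes were lower with RUNX1A than with RUNX1B (42 adjusted over the list alone; median log2 fold change -0.86, adjusted p = 4.51e-29), as were 38 of 40 G2/M genes, with none higher (39 adjusted over the list alone; median -1.16, adjusted p = 4.4e-30). CDT1, a replication licensing factor gene, stood at 34.6 ± 1.43 against 129 ± 3.78 TPM. Cholesterol synthesis genes were lower in 20 of 23 cases and higher in none (20 adjusted over the list alone; median -0.47, adjusted p = 9.25e-09), and unfolded protein and stress genes lower in 19 of 24 cases and higher in 3 (19 and 3 adjusted over the list alone; median -0.39, adjusted p = 5.05e-07). Of 29 p53 targets 21 were higher and 5 lower (22 and 6 adjusted over the list alone; median 0.34, adjusted p = 2.34e-05), with CDKN1A at 406 ± 10.4 against 227 ± 10.6 TPM. Immediate early genes were higher in 12 of 21 cases and lower in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0014). The list of cytarabine and nucleoside metabolism genes had 3 of 18 members higher and 11 lower (3 and 12 adjusted over the list alone; median -0.30, adjusted p = 0.00038), and its 3 named members TYMS, RRM1 and RRM2, which make deoxynucleotides, are also in the G1/S list.

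Between RUNX1A and RUNX1B 7124 genes passed the test, 3528 higher and 3596 lower with RUNX1A, and 580 and 830 of these differed at least 1.5-fold. Of the 33 lists 17 were called, 13 of them also without scaling between libraries. The 7 just described were also called with an estimated correlation. Without scaling between libraries the median of all genes was -0.115 on the log2 scale, the share of called genes that were higher was 23.6% in place of 49.5%, and 385 and 1253 genes were at least 1.5-fold higher and lower. Ribosomal protein genes were higher with RUNX1A in 31 of 36 cases and lower in none (31 adjusted over the list alone; adjusted p = 1.16e-08, and adjusted p = 0.165 with an estimated correlation), and mitochondrially encoded genes higher in 9 of 13 and lower in none (9 adjusted over the list alone; adjusted p = 0.00082, and adjusted p = 0.353 with an estimated correlation).

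The comparison of RUNX1C with RUNX1C NDel showed what differed with the N-terminal change at RUNX1 levels that did not pass the test for a difference. MMP9 stood at 96.3 ± 1.33 TPM with RUNX1C and 8.28 ± 0.569 with RUNX1C NDel (log2 fold change 3.39, SE 0.07, adjusted p = 2.88e-12), and BTG2 at 103 ± 1.86 against 38.1 ± 0.655 TPM (log2 fold change 1.41, SE 0.03, adjusted p = 2.88e-12). The B-cell adaptor gene BLNK stood at 12.9 ± 1.25 against 1.87 ± 0.445 TPM, and CIITA, the master regulator of MHC class II genes (ENSG00000179583.21, chromosome 16, 10866222 to 10943021), at 9.17 ± 0.252 against 3.60 ± 0.314 TPM (log2 fold change 1.14, SE 0.05, adjusted p = 5.72e-09). MYC was lower with RUNX1C (228 ± 5.27 against 378 ± 13.7 TPM), as was the metallothionein gene MT1G (31.0 ± 0.506 against 67.9 ± 2.84 TPM).

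Antigen presentation genes were higher with RUNX1C than with RUNX1C NDel in 14 of 16 cases and lower in 1 (14 and 2 adjusted over the list alone; median log2 fold change 1.13, adjusted p = 2.43e-10). Monocyte and macrophage genes were higher in 22 of 26 cases and lower in 1 (22 and 1 adjusted over the list alone; median 0.72, adjusted p = 1.12e-14), with ITGAX at 21.6 ± 0.737 against 8.97 ± 0.330 TPM. The adhesion and migration list had 12 of 16 members higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 2.32e-07), with ICAM3 at 148 ± 3.63 against 63.9 ± 1.7 TPM. NF-kB and inflammation genes were higher in 15 of 20 cases and lower in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.000206), and p53 targets higher in 15 of 29 and lower in 3 (16 and 4 adjusted over the list alone; adjusted p = 0.00122). Interferon response genes were higher in 13 of 30 cases and lower in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.00549), with IFITM1, an antiviral membrane protein gene, at 107 ± 4.39 against 21.5 ± 2.21 TPM. The T and NK cell list, of which 8 of 24 genes were measured, had 6 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.00479), with GNLY at 23.1 ± 0.913 against 2.14 ± 0.303 TPM. G1/S genes were lower in 39 of 42 cases and higher in none (41 adjusted over the list alone; median -0.35, adjusted p = 1.48e-20), and MYC targets and ribosome biogenesis genes lower in 31 of 34 and higher in none (32 adjusted over the list alone; median -0.37, adjusted p = 1.48e-20).

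Between RUNX1C and RUNX1C NDel 5465 genes passed the test, 2697 higher and 2768 lower with RUNX1C, and 515 and 77 of these differed at least 1.5-fold. Camera called 16 of the 33 lists, and the 9 just described were also called with an estimated correlation.

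The changes against control were next compared between constructs. Across genes, the log2 fold changes of RUNX1C and RUNX1C NDel had a Pearson correlation of 0.780 (covariance 0.128), RUNX1B and RUNX1C NDel 0.796 (covariance 0.0755) and RUNX1B and RUNX1C 0.676 (covariance 0.0870). RUNX1A had correlations of -0.016 with RUNX1B (covariance -0.00119), 0.069 with RUNX1C (covariance 0.00922) and -0.050 with RUNX1C NDel (covariance -0.00489). Leaving out control replicate 1, 2 or 3 gave 0.072, 0.070 and 0.070 for RUNX1A and RUNX1B, and 0.102, 0.130 and 0.115 for RUNX1A and RUNX1C. Leaving out 1 RUNX1A or RUNX1B library gave -0.047 to 0.011 for RUNX1A and RUNX1B, so the sign of that value is not fixed. These are correlations across genes, which are not independent replicates, and all share the same 3 control libraries, which are too few to divide between the comparisons. RUNX1, raised by each construct, is among the genes. Simulated groups with no change gave a mean correlation of 0.495 (range -0.219 to 0.850 over 100 simulations) and a mean covariance of 0.0140. They shared 3 mock controls drawn from the deviations of all 15 libraries, not the real controls. Deviations within a group cancel out, which may distort this range.

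At 1.5-fold, 422 genes were higher and 303 lower with both RUNX1C and RUNX1C NDel, against 34.5 and 21.8 expected from the numbers in each. RUNX1B and RUNX1C shared 213 higher and 139 lower genes, against 17.6 and 9.54 expected. RUNX1A and RUNX1C shared 61 higher and 32 lower genes, against 15.4 and 19.5 expected. In opposite directions 71 genes were lower with RUNX1A and higher with RUNX1C (28.6 expected) and 39 the reverse (10.5 expected). RUNX1A and RUNX1B shared 6 higher and 10 lower genes, against 3.28 and 4.84 expected. In opposite directions 46 were lower with RUNX1A and higher with RUNX1B (6.10 expected) and 37 the reverse (2.60 expected). These overlaps were counted with 1 added to TPM alone, and the shared higher genes include RUNX1 itself. Part of the excess of shared genes may come from the shared controls.

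**Figure D4:**
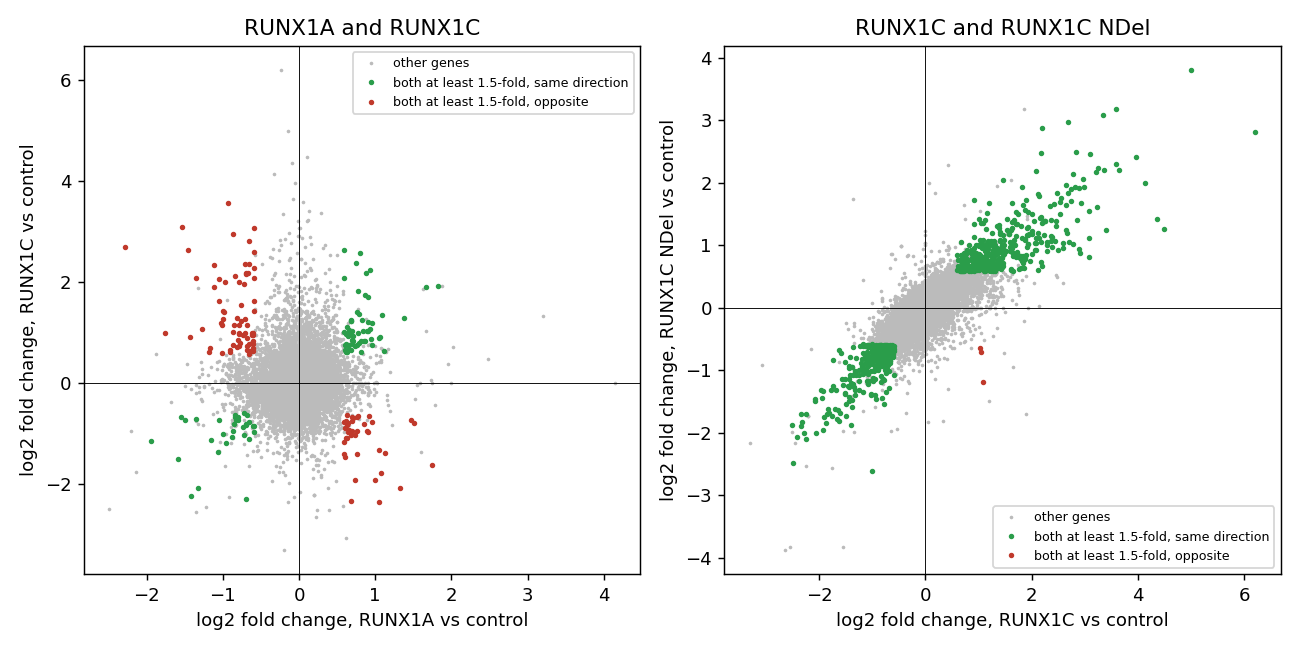
Log2 fold change against control of each gene tested except RUNX1, for RUNX1A (x axis) and RUNX1C (y axis) on the left and RUNX1C (x axis) and RUNX1C NDel (y axis) on the right. Points are genes, coloured where both changes reach 1.5-fold. The correlation across genes, RUNX1 included, is 0.069 on the left and 0.780 on the right.

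The authors' deposited tables compare pairs of constructs and list genes at more than a 2-fold change. They rest on the same libraries, and limma called 8674 of 15707 genes between RUNX1C and RUNX1A. Close agreement was therefore largely fixed in advance and is no separate evidence. Their table of RUNX1C against RUNX1A held 587 genes, 426 of them higher with RUNX1C. Of the 587 genes 350 had an adjusted p under 0.05 in the authors' deposited table, and 346 of the 350 were called in the same direction in the limma comparison (578 of all 587). The other genes include 90 with no adjusted p listed. Their table of RUNX1C against RUNX1B held 170 genes, 77 with an adjusted p under 0.05, of which 76 were called in the same direction (167 of all 170). No adjusted p was listed for 84. A table named RUNX1A against RUNX1B held 111 genes whose mean values lay within 5% of those of the RUNX1C and RUNX1C NDel libraries in 100% of cases, and of the RUNX1A and RUNX1B libraries in 0.901%. Read as RUNX1C against RUNX1C NDel, 39 of its genes had an adjusted p under 0.05, and all 39 were called in the same direction (109 of all 111). No adjusted p was listed for 72. In the authors' deposited tables the log2 fold change of BTG2 was 1.67, 2.09 and 1.46 in the order given here. That of MMP9 was 4.89 against RUNX1B and 3.55 against RUNX1C NDel. The authors' table also lists MMP9 as higher with RUNX1C than with RUNX1A. The fold is left out here, since the level with RUNX1A lies near 0 TPM.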

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

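The tests of scaling, of RUNX1 level, of a weaker response and of the deposited tables were chosen after the results were seen. The GC and length correction was added after the data were seen but before its own results were, and the splits of the libraries were set before.

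Some gene lists moved in opposite directions against control with different constructs, and the direct comparison of the constructs was called. Between RUNX1C and RUNX1A these were the G2/M list (median log2 difference 1.16), cholesterol synthesis (0.46) and ribosomal proteins (-0.27, adjusted p = 0.192 with an estimated correlation). Between RUNX1A and RUNX1B they were G1/S (-0.86), G2/M (-1.16), p53 targets (0.34), cytarabine and nucleoside metabolism (-0.30), unfolded protein and stress genes (-0.39), cholesterol synthesis (-0.47) and ribosomal proteins (0.28, adjusted p = 0.165 with an estimated correlation). Without scaling the p53 targets (0.19) and ribosomal proteins (0.13) of this pair, and the ribosomal proteins of RUNX1C and RUNX1A (-0.16), kept their direction but were smaller by more than 1.5 times. The G1/S list differed between RUNX1C and RUNX1B (-0.31) and between RUNX1C and RUNX1C NDel (-0.35), and its fall with RUNX1C against control was not called with an estimated correlation (adjusted p = 0.194). With an estimated correlation the following changes against control were also not called: ribosomal proteins with RUNX1C (adjusted p = 0.439), RUNX1A (adjusted p = 0.351) and RUNX1B (adjusted p = 0.183), cytarabine genes with RUNX1A (adjusted p = 0.0672) and RUNX1B (adjusted p = 0.182), and stress genes with RUNX1B (adjusted p = 0.0708).

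Single genes that changed at least 1.5-fold in opposite directions against control, with the difference between the constructs called, numbered 71 higher with RUNX1C and lower with RUNX1A and 39 the reverse. There were 46 lower with RUNX1A and higher with RUNX1B and 37 the reverse. Against RUNX1B, 4 genes were higher with RUNX1C and lower with RUNX1B (BLNK, HLA-DRB1, HLA-DRB5 and HLA-DRA), and 3 of them (BLNK, HLA-DRB1 and HLA-DRA) were higher with RUNX1C and lower with RUNX1C NDel. Both counts lay below those expected from the numbers in each (14.0 and 32.1). These names were chosen after their values were seen.

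The first pattern weighed is the lower level of cell cycle genes with RUNX1A than with RUNX1B (80 of 82 genes of the G1/S and G2/M lists lower, median log2 difference -1.02). Without scaling 81 were lower (median -1.16). Dropping the scaling moved the median of all genes of this pair from 0.006 to -0.115, so that outcome was fixed in advance. It shows only that scaling did not create the lower level. After GC and length trends were removed 80 were lower (median -0.996), which argues against those trends as the whole cause. A steady fall with rising RUNX1 RNA is argued against by the G2/M median of 0.33 with RUNX1B over control. An effect of RUNX1 RNA above a level reached by RUNX1A alone cannot be told apart from an effect of the isoform, since 0 libraries of other groups reach the lowest RUNX1A library (639 TPM; the highest other is 552 TPM). A difference between the isoforms themselves may be the source and stays open.

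The second pattern is the excess of genes higher with RUNX1C than with RUNX1C NDel (515 higher and 77 lower at 1.5-fold). RUNX1 RNA differed by 0.072 on the log2 scale between the constructs, and 507 of the 583 genes with known GC content and length were still called at 1.5-fold after those trends were removed, so the tables argue against both as the whole cause. A weaker response of the same kind with RUNX1C NDel is argued against for 87 of the 515 genes (16.9%), which were lower with RUNX1C NDel than in control (50 of the 87 higher with RUNX1C and 11 lower with both), and for 7 of the 14 antigen presentation genes that were higher with RUNX1C. These calls had no fold minimum, and choosing genes higher with RUNX1C than with RUNX1C NDel favours genes low with the latter. At 1.5-fold only 3 genes were higher with RUNX1C and lower with RUNX1C NDel than in control (32.1 expected). Far more were higher (422) or lower (303) with both. The weaker response stays open for the 262 genes higher with both constructs and the 166 not called with RUNX1C NDel against control, and protein levels were not measured. The N-terminal change itself may be the source, as a hypothesis.

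The third pattern concerns the authors' deposited tables, of which the one named RUNX1A against RUNX1B (111 genes) was not used under that name. Its mean levels lay within 5% of those of RUNX1C and RUNX1C NDel from rounded TPM for 100% of its genes, and of those of RUNX1A and RUNX1B for 0.901%, consistent with a table under the name of another pair. For each of the 3 deposited pairs, 100% of the genes lay within 5% of means from TPM rounded to whole numbers. With unrounded TPM it was 97.6%, 96.5% and 98.2%, fewer for each pair. These means alone cannot tell a test on rounded TPM from 1 on unrounded TPM, since both lie within the 5% allowed for most genes. Either way the means match TPM values, which are not counts. No biological explanation was tested.

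The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. Every other split mixed both groups on each side, which moves the difference between the groups into the spread. Low counts in the other splits were thus fixed in advance wherever the groups were clearly apart, and no conclusion is drawn from them. The real split gave 4859 genes for RUNX1A against control (highest other split 2), 4118 for RUNX1B (2), 8070 for RUNX1C (1) and 5996 for RUNX1C NDel (1). It gave 8674 for RUNX1C against RUNX1A (2), 6392 for RUNX1C against RUNX1B (1), 7124 for RUNX1A against RUNX1B (2) and 5465 for RUNX1C against RUNX1C NDel (1). For the test of any difference among the 5 groups, the real split was the 1 of 100 with as many genes (10274, highest other 6242). This argues against a random division of these libraries. It cannot tell an effect of the constructs from differences between single cultures, since the labels do not state separate cultures.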

How the results depend on the processing

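The pseudocounts, the GC and length correction and the fit without a variance trend were chosen after seeing the data. Counts of called genes at an adjusted p under 0.05 stayed within 1.5 times the reported count under every alternative run except a fold minimum. A pseudocount of 2 TPM lowered the 1.5-fold count of every comparison, though by less than 1.5 times.

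With at least 1.5-fold required, 3470 genes differed among the 5 groups, 606 with RUNX1A, 436 with RUNX1B, 1916 with RUNX1C and 917 with RUNX1C NDel against control, 2451 between RUNX1C and RUNX1A, 932 between RUNX1C and RUNX1B, 1410 between RUNX1A and RUNX1B and 592 between RUNX1C and RUNX1C NDel, since fewer genes meet both conditions. With a pseudocount of 0.1 TPM the 1.5-fold counts were 1006 for RUNX1A, 811 for RUNX1B and 1530 for RUNX1C NDel against control, 1446 for RUNX1C against RUNX1B, 2148 for RUNX1A against RUNX1B and 969 for RUNX1C against RUNX1C NDel; a smaller pseudocount shrinks the changes of weakly expressed genes less. With an estimated correlation the number of lists called was 9 with RUNX1A, 5 with RUNX1B, 7 with RUNX1C and 4 with RUNX1C NDel against control, 5 for RUNX1C against RUNX1A, 7 for RUNX1C against RUNX1B, 7 for RUNX1A against RUNX1B and 9 for RUNX1C against RUNX1C NDel. Of the lists called with scaling, 12 of 14 with RUNX1C and 9 of 10 with RUNX1C NDel against control and 13 of 17 for RUNX1A against RUNX1B were called without it. In the other 5 comparisons none was lost.

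For genes with a mean of at least 10 TPM the correlations across genes were -0.189 for RUNX1A and RUNX1B, -0.011 for RUNX1A and RUNX1C, 0.748 for RUNX1B and RUNX1C and 0.838 for RUNX1C and RUNX1C NDel; the cause was not tested. Without scaling the changes of PLEK and XBP1 between RUNX1A and RUNX1B reversed to -0.049 and -0.0038 and did not pass the test; the median of all genes of that pair was -0.115 in this setting.

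Leaving out each library gave 4062 to 4487 genes for RUNX1A, 3402 to 3573 for RUNX1B, 7331 to 7540 for RUNX1C and 5258 to 5462 for RUNX1C NDel against control, and no count moved by more than 1.5 times; the correlations of RUNX1A with RUNX1B ran from -0.047 to 0.072 and with RUNX1C from 0.055 to 0.130, highest without a control library. With the replicate number as a block 4833 genes changed with RUNX1A, and of the lists called without it 13 of 14 were called with RUNX1C against control, 11 of 12 for RUNX1C against RUNX1B and 16 of 17 for RUNX1A against RUNX1B. Deviations of libraries with the same number correlated by -0.065 to 0.130 between groups, while 10 of the 15 libraries were closest to a library of their own number. With 3 replicate numbers per group, that is more than unrelated numbers would give on average. Whether the numbers mark a shared day stays open, and they were not treated as pairs. Of 12662 values of named genes under the alternatives, 12579 kept their direction and call, 81 lost the call (41 of these on leaving out a library and 16 without scaling) and 2 reversed. A DESeq2 test, planned as an alternative to the edgeR test, was not run, since it needs counts. The depth is unknown, so no limit from depth can be given.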

Other observations

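The series title concerns chemoresistance, and no drug was given in these samples. Genes of cytarabine handling went in different directions. CDA, a cytidine deaminase that inactivates cytarabine, stood at 6.51 ± 0.777 TPM with RUNX1C and 3.91 ± 0.990 with RUNX1C NDel against 0.0833 ± 0.0321 in control. SAMHD1, which degrades deoxynucleotides and active cytarabine, stood at 302 ± 7.17 TPM with RUNX1C, 179.9 ± 1.38 with RUNX1C NDel and 164 ± 11.1 with RUNX1B against 106 ± 3.84 in control. SLC29A1, a nucleoside importer, stood at 34.7 ± 1.12 TPM with RUNX1C against 50.6 ± 0.813 in control. The whole list was not called with RUNX1C against control, with 5 of 18 members higher and 9 lower (5 and 9 adjusted over the list alone; median log2 fold change -0.08, mean 0.10, adjusted p = 0.481). Camera called it in opposite directions with RUNX1A (median -0.16, adjusted p = 0.00174) and RUNX1B (median 0.05, adjusted p = 0.0266). Neither call held with an estimated correlation (adjusted p = 0.0672 and 0.182).

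The BCL2 family list, which holds both inhibitors and activators of apoptosis, was not called in any of the 8 comparisons, with or without scaling. With RUNX1C 7 of 15 members were higher and 3 lower than in control (7 and 3 adjusted over the list alone; adjusted p = 0.315), among them the activators BCL2L11 (43.5 ± 1.52 against 19.8 ± 2.65 TPM) and BMF (19.5 ± 0.136 against 9.66 ± 0.260 TPM). The list of drug efflux transporters had 6 of 9 members higher and 1 lower with RUNX1C (6 and 1 adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.11 with an estimated correlation), with ABCA2 at 60.7 ± 1.16 against 26.7 ± 1.14 TPM.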
